A study of Drosophila melanogaster with 30 samples.

How the data were processed

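Poly(A)-selected RNA from the anterior and posterior midgut of adult female flies was sequenced in 30 libraries, 3 for each of 5 conditions in 2 regions, from a library kit that does not mark strand. Per the submitters' processing notes, reads were split with bcl2fastq 2.17.1.14, aligned with TopHat2 2.1.1 and Bowtie2 2.2.9 to dm6 with the BDGP6 annotation, and quantified with Cufflinks 2.2.1. The treatment of reads with several matching places is not given in the sources used here. The deposited values are gene FPKM with lower and upper confidence limits and a status, per the file headers, in 1 table per library with 17488 genes each. FPKM is a share of each library corrected for gene length, so a few very abundant genes lower all others.

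From these values 103 genes with a failed estimate in at least 1 library were left out (1 to 23 failed estimates per library). Each library was then divided by a median-of-ratios factor over the 8584 genes above 0 in all libraries (0.537 to 1.2 in anterior and 1.03 to 1.45 in posterior libraries). Values were transformed to log2 with a pseudocount of 1, and the 8335 genes with a mean scaled FPKM of at least 1 over all libraries were tested. Limma 3.58.1 in R 4.3.3 fitted the 10 group means with 20 residual degrees of freedom and a trend in the prior variance, and all tests were 2-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, so every adjusted p of a gene here comes from limma. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. The comparisons were posterior against anterior on the control diet, each condition against the control group within each region, and the difference of each response between regions.

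In all, 30 gene lists were fixed. The lists of processes were sterol transport and handling, digestive lipases, fatty acid synthesis and the SREBP pathway, triglyceride storage and lipid export, fatty acid beta-oxidation, trypsins and Jonah proteases, amylases and maltases, antimicrobial peptides and PGRPs, the Notch pathway, JAK/STAT and EGFR ligands and targets, the cell cycle, detoxification enzymes, heat shock proteins, the unfolded protein response, ecdysone signalling, regional transcription factors, cytosolic ribosomal proteins and oxidative phosphorylation. The lists of cell and tissue markers were enterocyte, intestinal stem cell and enteroblast, enteroendocrine cell, visceral muscle, fat body, ovary and germline, and Malpighian tubule. The copper cell, hemocyte, trachea, neuron and hindgut lists had 2, 2, 1, 1 and 0 members among the tested genes, under the 3 needed, and have no list result. Of 30 Notch pathway genes 29 were matched in the files, all but E(spl)m1, and 15 were tested. The other 25 lists were tested with fry, with adjusted p over the lists within a comparison, and again with camera and an estimated correlation. The PValue of fry tests whether the genes of a list move, on balance, one way, and its mixed PValue whether they change in either direction, and neither compares the list with other genes. Camera with an estimated correlation called 3 list tests: the sterol list and the Notch list named with the regions and the lipid-depleted diet, and the digestive lipases in the region difference on high cholesterol (adjusted p = 0.0428, against 0.135 by fry).

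Genes were named by a fixed rule. Hr96 was given in every library. In each comparison the 6 largest rises and 6 largest falls among called genes with no overlap between groups were named, then up to 3 passing members with the largest change in the direction of each list that fry called. For the sterol, digestive lipase, Notch, enteroendocrine and stem cell lists up to 3 genes with the smallest adjusted p were named whether they passed or not, and for each region difference the 5 genes with the smallest adjusted p. A name outside the rule is marked as chosen after its values were seen. Positions are those in the deposited tables, in dm6. Genes that overlap another gene, close paralogs and RNAs too short for this kind of library are uncertain.

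Depth was read from the values themselves. Where 613 genes had implied fragment numbers of up to 30 in at least 20 libraries, the step between low values gave a relative depth per library, and 52.5% of values under 10 implied fragments were whole within 0.02. The mean squared difference between 2 libraries of a group was 1.86 to 8.69 times the sampling noise implied by the confidence limits. The spread between replicates thus exceeded sampling noise in each pair, though at 1.86 (anterior lipid-depleted replicates 2 and 3) noise was the larger part of it.

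The test was run on simulated data for the anterior lipid-depleted comparison, with 8335 genes (200 changed) and 20 draws. It recovered 67.9% of genes changed by log2 1 and 91.9% of those changed by log2 2, with 0 in the wrong direction and a false share of 4.98%. A list shifted by log2 0.5 was found in 20 of 20 draws, and 1 of 480 other list tests was called. Correlated genes were not simulated.

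Alternatives were FPKM as deposited without rescaling, quantile normalization, pseudocounts of 0.1 and 5, no filter, a mean of at least 5, failed estimates kept, a fit of only the compared groups, robust variance moderation, the replicate number as a block, each library left out in turn, and camera for the lists. Fits of replicates 2 and 3 alone, and with these averaged into 1 library, were added after the data were seen. The groups, the tests, the lists, the naming rule and the other alternatives were chosen before the data were examined. The sequence reads, splice forms and confidence limits were left out of the tests, and reads were not analysed here.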

Results

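The series asked how sterol and fat in the diet, and the nuclear receptor Hr96, which responds to cholesterol, act on the adult fly midgut, with Notch signalling and the making of new gut cells as its theme. Poly(A) RNA was profiled from the anterior and the posterior midgut of mated Drosophila females aged 10 to 12 days. Wild-type y[1]w[1] flies ate a control, a lipid-depleted or a high-cholesterol diet (0.2% cholesterol, 4 times the control level), and the strains Hr96[1] and Hr96[2x] were kept on the control diet. The 5 conditions, 2 regions and 3 replicates gave 30 libraries in 10 groups of 3, each made from 30 to 50 dissected regions. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical.

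The files hold FPKM and no read counts, so absolute depth is unknown. From the steps between low values, relative depth ran from 0.794 in anterior lipid-depleted replicate 3 to 1.37 in posterior Hr96[2x] replicate 1, and 9923 to 13355 genes were above 0 per library. The 10 most abundant genes held 16.6% to 38.1% of the FPKM total in the anterior libraries and 10.3% to 17.3% in the posterior ones. Replicates 2 and 3 were the closest pair in 8 of 10 groups. If these 2 libraries shared their tissue, n would be below 3, and counts with them averaged are given with the effects of processing. Levels below are scaled FPKM as mean ± SD (SD, n = 3), and fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. The 3 libraries of a group against 3 of another cannot give an exact permutation p below 0.1, and 10% of genes would show no overlap between groups by chance.

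Region was the main axis of variation, at 35.1% of the variance, and strain was the next, at 13.7%. Anterior libraries lay between 23.19 and 57.15 on the first component and posterior libraries between −53.07 and −29.68. On the second component all 18 wild-type libraries lay between 12.32 and 32.51, and all 12 libraries of the Hr96 strains between −44.48 and −15.91.

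**Figure D1:**
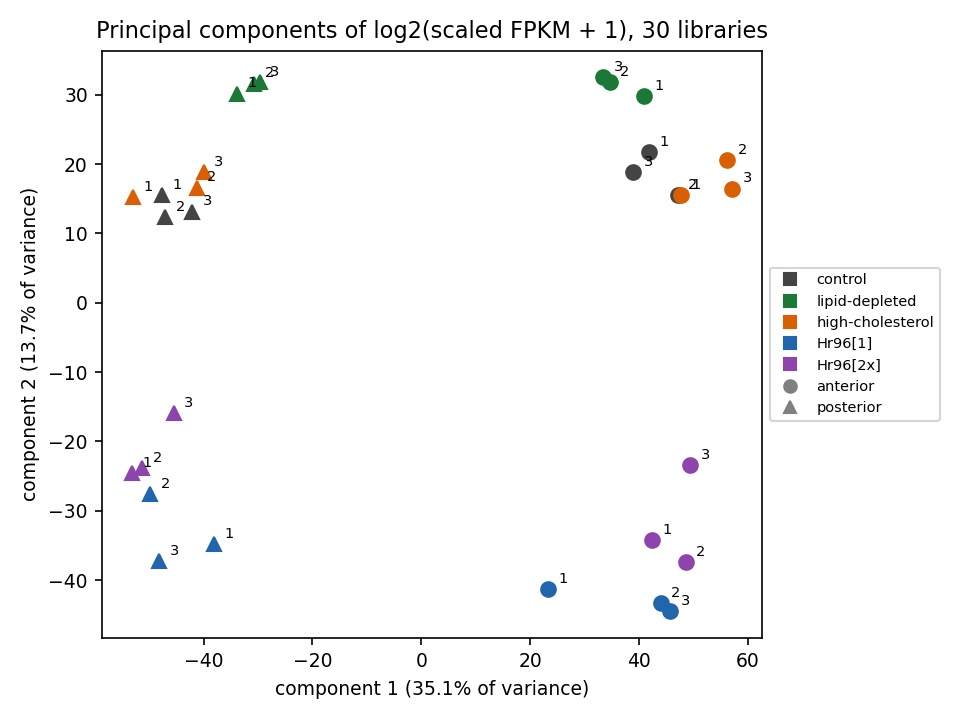
Principal components 1 (35.1% of variance) and 2 (13.7%) of log2(scaled FPKM + 1) in the 30 libraries, 1 point per library, coloured by condition and shaped by region. Regions separate on component 1, and the 12 libraries of the Hr96 strains lie at or below −15.91 on component 2.

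Hr96 (FBgn0015240, chromosome 3R, 25025235 to 25029351, dm6) was read first, as the gene the strains are named for. In wild type on the control diet it stood at 67.9, 43.4 and 61.2 in anterior replicates 1 to 3 and at 65.2, 57.8 and 63.1 in posterior ones. In Hr96[1] it stood at 42.1, 40.3 and 33.9 in anterior and at 38.1, 33.4 and 27.9 in posterior libraries. Its posterior level of 33.1 ± 5.12 against 62.0 ± 3.81 was a fall (log2 −0.89, SE 0.244, adjusted p = 0.0173), and the anterior difference was not (log2 −0.54, adjusted p = 0.112; 0.0118 on FPKM as deposited). Without posterior Hr96[1] replicate 3 the adjusted p was 0.0893, and the call was also lost without control replicate 1 or 3. In Hr96[2x] it read 76.5, 69.3 and 80.0 in anterior and 73.4, 63.7 and 80.3 in posterior libraries, not called against control in either region (log2 0.40, adjusted p = 0.283; log2 0.22, adjusted p = 0.669). A transcript level does not show whether Hr96[1] makes working receptor. The construction of either strain is not given in the sources used here.

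Hr96 itself rose on both altered diets in the anterior midgut. On the lipid-depleted diet it read 179, 121 and 128 in anterior libraries (log2 1.30, SE 0.244, adjusted p = 0.00271; 0.066 in a fit of the compared groups alone) and 121, 96.1 and 111 in posterior ones (log2 0.80, adjusted p = 0.073; 0.0246 on FPKM as deposited and 0.00894 after quantile normalization). On the high-cholesterol diet it read 84.9, 143 and 172 in anterior libraries (log2 1.16, adjusted p = 0.00984) and 68.9, 127 and 143 in posterior ones (log2 0.79, adjusted p = 0.166; 0.00921 without replicate 1). The anterior high-cholesterol call gave adjusted p = 0.0786 on FPKM as deposited and 0.118 without replicate 3, and was also lost without replicate 2 or control replicate 2.

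The posterior and the anterior midgut on the control diet were compared to show which digestive and lipid genes divide the regions. The trypsin epsilonTry (FBgn0010425, 2R, 11345237 to 11346066) stood at 6026 ± 1680 in the anterior and 4.98 ± 2.05 in the posterior midgut (log2 −10.01, SE 0.617, adjusted p = 7.78e-11). The Jonah proteases Jon25Bii, Jon25Bi and Jon74E and the lipase CG6295 were also anterior (log2 −9.36, −9.26, −9.21 and −9.76). So was CG34026 (log2 −9.35). Jon99Fi (log2 8.22), Jon99Fii (8.06), iotaTry (7.72) and the protease genes CG11911 (9.37) and CG17571 (8.60) were posterior, beside CG8628 (9.22), CG12057 (8.96), CG32284 (8.70) and CG15254 (8.65). Of 20 trypsins and Jonah proteases, 10 were higher in the posterior midgut and 5 lower, against 11 and 5 adjusted over the list alone. The list moved up (fry adjusted p = 0.00041; adjusted p = 0.854 with an estimated correlation). Jonah and trypsin genes are close copies, and reads divided between them make their single values uncertain.

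Sterol genes lay on the posterior side. The lipase mag (magro, FBgn0036996, 3L, 20460683 to 20462274), which also splits cholesterol esters, stood at 99.3 ± 12.9 in the posterior and 0.826 ± 0.475 in the anterior midgut (log2 5.80, SE 0.77, adjusted p = 6.21e-06). The sterol-binding genes Npc2d (log2 6.45) and Npc2b (2.18) and the predicted sterol acyltransferase CG8112 (3.46) were posterior too. Of 14 sterol transport and handling genes, 9 were higher and 1 lower, against 10 and 1 adjusted over the list alone. This list passed both tests (fry adjusted p = 2.26e-09; adjusted p = 0.00215 with an estimated correlation). Triglyceride storage and export genes were higher as a list (3 of 10, also 3 adjusted over the list alone; fry adjusted p = 0.0368; adjusted p = 0.931 with an estimated correlation). They included the lipid droplet gene Lsd-1 (log2 2.49, adjusted p = 0.00329; 0.0976 with a pseudocount of 5), CG3209 (1.48) and Lpin (1.16). Digestive lipases went both ways (6 higher and 2 lower of 12, 7 and 2 adjusted over the list alone; fry adjusted p = 0.0814). CG8093 was higher (log2 3.93) and CG17192 lower (log2 −6.25).

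Enteroendocrine peptides also divided the regions. CCHa1 (FBgn0038199, 3R, 14092504 to 14096835) stood at 37.7 ± 10.4 in the posterior and 0.973 ± 0.799 in the anterior midgut (log2 4.35, SE 0.31, adjusted p = 5.17e-10). AstA was posterior (log2 6.05) and the orcokinin gene CG13565 anterior (log2 −2.90). Of 13 enteroendocrine genes 3 were higher and 2 lower, the same numbers adjusted over the list alone (fry adjusted p = 0.0992, up, with the median at log2 −0.26 and the mean at 0.35). In the Notch list the γ-secretase subunit aph-1 was higher (log2 0.69, adjusted p = 0.00456) and the ligand-activating ligase mib1 lower (log2 −0.53, adjusted p = 0.00942; 0.652 on FPKM as deposited). The glycosyltransferase fng (log2 −0.41, adjusted p = 0.178) and the stem cell genes Dl (0.51, 0.208), Sox21a (0.40, 0.582) and klu (−0.21, 0.676) were not called. With the replicate number as a block fng (0.0287) and Dl (0.0166) were. The unfolded protein response list was lower (1 of 11 fell, 2 adjusted over the list alone; fry adjusted p = 0.0175; adjusted p = 0.854 with an estimated correlation) through Xbp1 (log2 −0.54, adjusted p = 0.0252). Its direction turned on FPKM as deposited (adjusted p = 0.934). The Xbp1 call was lost there (0.622), after quantile normalization (0.079) and without any single library but posterior control replicate 1 (0.105 without posterior control replicate 2).

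In all, 1222 of 8335 genes differed between regions, 573 higher and 649 lower in the posterior midgut, 699 of them by at least log2 1. No overlap between groups was seen in 1183 of them and in 36.6% of all genes. The deposited scale gave 1687, 1392 higher and 295 lower, with the median of all genes at log2 0.35. With the replicate number as a block the count was 2267.

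**Figure D2:**
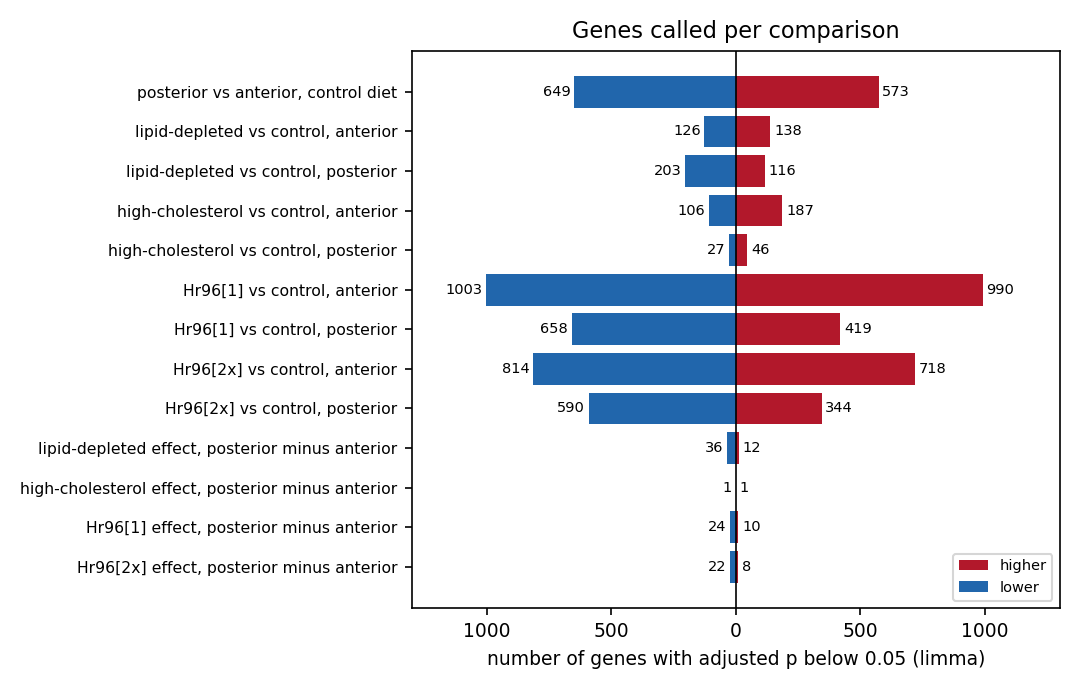
Number of genes called at an adjusted p of 0.05 in each comparison, with genes higher in the group named first to the right and genes lower to the left, and differences between regions in the last 4 bars. Hr96[1] against control in the anterior midgut has the longest bars, 990 higher and 1003 lower.

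The lipid-depleted diet was compared with the control diet to show the response of each region to the loss of dietary fat and sterol. In the anterior midgut the sterol uptake gene Npc1b (FBgn0261675, X, 20934869 to 20939503) rose from 46.9 ± 17.5 to 445 ± 25.4 (log2 3.29, SE 0.446, adjusted p = 9.82e-05). Npc2e (FBgn0051410, 3R, 10053332 to 10054348) rose from 616 ± 283 to 4251 ± 1290 (log2 2.87, adjusted p = 2.59e-05). The lipophorin receptor gene LpR1 fell (log2 −2.48, adjusted p = 0.0047). The serine protease genes CG18179 (log2 −4.73, adjusted p = 4.07e-08) and CG18180 (log2 −4.13) fell. So did the lipase genes CG31091 (FBgn0051091, 3R, 25899903 to 25902172; log2 −3.34) and CG31089, listed at 0 in all 3 lipid-depleted libraries. CG7567, CG9825, CG15695 and CG9864 completed the largest falls (log2 −4.55 to −3.42). The largest rises were in CG31468 (log2 4.89), CG6283, which lies within RYa-R (4.19), the transporter gene prt (3.88), CG8628 (3.69), Cyp4s3 (3.46) and CG15534 (3.39).

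The Notch regulator fng (FBgn0011591, 3L, 20925891 to 20949512), which adds sugars to the receptor, rose in the anterior midgut from 5.74 ± 0.8 to 11.6 ± 0.965 (log2 0.91, SE 0.189, adjusted p = 0.00765). The gene aph-1 (FBgn0031458, 2L, 2766233 to 2767281) rose from 21.0 ± 2.19 to 35.4 ± 3.26 (log2 0.73, adjusted p = 0.013). Its call was lost without control replicate 2 (0.0622) or 3 or lipid-depleted replicate 1. These were 2 of 15 Notch pathway genes, also 2 adjusted over the list alone (fry adjusted p = 0.105). The peptide genes CCHa1 (0.973 ± 0.799 to 4.49 ± 1.78, adjusted p = 0.0067) and AstA (log2 1.95, adjusted p = 0.0143) rose from low levels, 2 of 13 enteroendocrine genes and 2 adjusted over the list alone (fry adjusted p = 0.376). Without lipid-depleted replicate 2 AstA gave 0.107, and without control replicate 2 CCHa1 gave 0.0777; pseudocount 5 also ended both calls (0.0623 and 0.0641). No stem cell gene was called (esg log2 0.41, adjusted p = 0.616; Dl 0.33, 0.686; fry adjusted p = 0.828), nor were mib1 (−0.21, 0.589) or 7B2 (0.61, 0.245). Of 14 sterol genes 3 rose and 1 fell, against 3 and 2 adjusted over the list alone (fry adjusted p = 0.105).

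Limma called 264 genes in the anterior comparison, 138 higher and 126 lower, 175 by at least log2 1, with no overlap in 261 of them and in 20.9% of all genes. With FPKM as deposited 251 were called, 188 higher and 63 lower, and the median of all genes was log2 0.12. The count was 144 without lipid-depleted replicate 2, 141 without replicate 3 and 115 without control replicate 2. Calls were lost for CG8628 without lipid-depleted replicate 2 (adjusted p = 0.225), and for CG7567 (0.133), CG6283 (0.0894) and CG18180 (0.0528) without control replicate 2. By fry 0 of 25 lists passed in the anterior midgut, where 1167 single genes had an unadjusted p under 0.05. Control replicate 1 differed from the other control libraries in fat body genes, with a mean log2 level of 6.11 against 3.41 and 3.46 in the anterior and 6.32 against 2.90 and 3.73 in the posterior midgut.

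The posterior midgut again showed a rise of fng, from 4.13 ± 1.06 to 8.77 ± 0.751 (log2 0.95, SE 0.189, adjusted p = 0.00421; 0.0719 in a fit of the compared groups alone). The rise of aph-1 (log2 0.70, adjusted p = 0.0136) lost its call without control replicate 2 (0.0788) or 1 or lipid-depleted replicate 1. The Notch list moved up (fry adjusted p = 0.000722; adjusted p = 0.025 with an estimated correlation; 0.0906 on FPKM as deposited). Of its 15 genes 2 were called over all genes and 2 adjusted over the list alone, and nct was not called (log2 0.39, adjusted p = 0.167; 0.039 after quantile normalization). Visceral muscle markers stood at a mean log2 level of 4.82, 4.03 and 4.29 in these libraries against 4.83, 5.02 and 5.08 in control (fry adjusted p = 0.2), and at 3.43 to 3.78 against 4.28 to 4.57 in the anterior midgut (0.227). Stem cell genes were not called one by one (esg 18.3 ± 3.9 against 10.2 ± 3.06, log2 0.81, adjusted p = 0.139; hdc 0.88, 0.258, or 1.36, 0.045 without lipid-depleted replicate 1; N 0.52, 0.292) or as a list (fry adjusted p = 0.118). Reads over fng may include the overlapping CG10589, since the libraries do not mark strand.

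Npc2e rose in the posterior midgut too (log2 1.39, adjusted p = 0.0195), a call lost without control replicate 1 (0.163) or lipid-depleted replicate 1 or 2. CG8112 fell from 86.8 ± 53 to 7.12 ± 1.34 (log2 −3.29, adjusted p = 1.67e-05) and Npc2a was not called (log2 1.15, adjusted p = 0.0563; 0.00647 after quantile normalization). The sterol list gave 1 rise and 1 fall of 14, against 5 and 3 adjusted over the list alone (fry adjusted p = 0.994, up, with the median at log2 0.14 and the mean at −0.30). The transporter gene prt (FBgn0043005, 3R, 23696372 to 23699027) rose from 1.79 ± 1.25 to 60.1 ± 6.3 (log2 4.56, adjusted p = 8.32e-05). The tyrosine hydroxylase gene ple (FBgn0005626, 3L, 6713356 to 6719525) rose from 1.4 ± 0.395 to 47.6 ± 5.98 (log2 4.35, adjusted p = 2.98e-06). The other large rises were in the amylase-related gene Amyrel (3.78), CG31468 (3.72), the lipase gene Lip3 (3.62, adjusted p = 0.0179; 0.0824 without control replicate 2) and the copper importer gene Ctr1B (3.57, adjusted p = 1.7e-05). Large falls were in CG12057 (log2 −5.53), CG32284 (−5.09), CG8299 (−4.81), CG31091 (−4.64), CG30043 (−4.64) and CG31089 (−2.80). The 87-base tRNA:SeC (log2 −7.35, adjusted p = 0.0159) is too short for a sure value in poly(A) RNA.

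In the posterior comparison 319 genes were called, 116 higher and 203 lower, 213 by at least log2 1, with no overlap in 318 of them and in 22.7% of all genes. The deposited scale gave 282, 135 higher and 147 lower, with the median at log2 0.12. The count was 179 without lipid-depleted replicate 2, 178 without replicate 3, 146 without control replicate 1 and 196 without control replicate 2. Enteroendocrine genes had no call (sc log2 0.53, adjusted p = 0.241; CCHa1 0.69, 0.285; Rab3 0.40, 0.313; fry adjusted p = 0.332).

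The high-cholesterol diet was compared with the control diet to show the response to excess sterol. Anterior Npc2e rose from 616 ± 283 to 3257 ± 1050 (log2 2.47, adjusted p = 0.000534), the same direction as on the lipid-depleted diet. Npc1b rose from 46.9 ± 17.5 to 282 ± 169 (log2 2.41, adjusted p = 0.00458; 0.0623 without high-cholesterol replicate 3). These were 2 of 14 sterol genes, 2 adjusted over the list alone (fry adjusted p = 0.121; Start1 not called, log2 0.32, adjusted p = 0.392). Ctr1B (FBgn0062412, 3R, 8317612 to 8319205) rose from 32.7 ± 7.44 to 445 ± 114 (log2 3.72, adjusted p = 6.97e-05). The metallothionein gene MtnA (FBgn0002868, 3R, 9783407 to 9784370) fell from 1655 ± 717 to 361 ± 238 (log2 −2.45, adjusted p = 0.0324). The MtnA call was lost without any single library of the 6 (0.107 without high-cholesterol replicate 1).

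Genes of fatty acid metabolism moved up in the anterior midgut on high cholesterol. Of 15 beta-oxidation genes 4 rose, 11 adjusted over the list alone (fry adjusted p = 0.00641; adjusted p = 0.194 with an estimated correlation; 0.761 on FPKM as deposited). They included the thiolase gene yip2 (131 ± 2.81 to 224 ± 23.4, log2 0.76, adjusted p = 0.0087), the carnitine transferase gene CG2107 (0.70, 0.0162) and the isomerase gene CG4594 (0.82). Of 10 fatty acid synthesis genes 3 rose, 5 adjusted over the list alone (fry adjusted p = 0.0192; adjusted p = 0.288 with an estimated correlation; 0.553 on FPKM as deposited). These were bgm (log2 2.23), the fatty acid synthase gene CG3523 (1.79) and AcCoAS (1.27). Antimicrobial peptide and PGRP genes moved down, with 2 of 18 called and 2 adjusted over the list alone (fry adjusted p = 0.00801; adjusted p = 0.194 with an estimated correlation). AttC (FBgn0041579, 2R, 13393705 to 13394667) fell from 9.35 ± 4.09 to 0.429 ± 0.207 (log2 −2.78, adjusted p = 2.11e-05) and PGRP-SD by log2 −1.99 (adjusted p = 0.0474). Each call here except AttC was lost without high-cholesterol replicate 3, from 0.0571 for CG2107 to 0.35 for PGRP-SD, and without replicate 2. Those of yip2, CG2107, CG4594, CG3523 and AcCoAS were lost on FPKM as deposited (0.327, 0.487, 0.205, 0.0616 and 0.062). Visceral muscle markers stood lower in the same libraries, at a mean log2 level of 4.21, 3.73 and 3.92 against 4.28, 4.57 and 4.39 in control (fry adjusted p = 0.297).

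Other large anterior rises were in CG6283 (log2 5.68, but 0.17 in replicate 1 alone), Jon25Biii (3.94), the serine synthesis gene aay (3.60), CG4734 (3.25) and Diedel3 (2.99). Falls were in CG4716 (−3.43), CG13117 (−3.27), CG15695 (−2.47) and the 228-base CR44404, listed at 0 in all 3 high-cholesterol libraries. All of these but CG6283 and CG4734 lost their call without replicate 3, from 0.0623 for CG13117 to 0.273 for Jon25Biii. Of 12 digestive lipases CG17191 and another member rose (CG17191 log2 2.33, adjusted p = 0.0284; 0.273 without replicate 3) and CG31091 fell (−2.23, 0.0193; 0.134). This compares with 5 rises and 2 falls adjusted over the list alone (fry adjusted p = 0.121). The prohormone chaperone gene 7B2 (FBgn0041707, 3R, 5376780 to 5377975) rose (log2 1.08, adjusted p = 0.0195; 0.0912 on FPKM as deposited and 0.194 without replicate 3), 1 of 13 enteroendocrine genes and 3 adjusted over the list alone (fry adjusted p = 0.121). Tk (0.89, 0.12) and amon (0.81, 0.131) were not called. No Notch gene was called (mib1 −0.21, 0.508, or 0.0435 on FPKM as deposited; aph-1 0.21, 0.581; E(spl)mbeta-HLH 0.61, 0.586; fry adjusted p = 0.96). Stem cell genes had no call either (Sox21a log2 −0.99, adjusted p = 0.159, or 0.0471 on FPKM as deposited; hdc −0.66, 0.423; mira 3.67 ± 0.691 to 11.4 ± 8.21, 0.255; fry adjusted p = 0.96). Without high-cholesterol replicate 1 calls were gained for mira (log2 1.80, adjusted p = 0.0238), Sox21a (−1.30, 0.0471), Tk (1.16, 0.032) and amon (1.12, 0.0213).

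The anterior count was 293 genes, 187 higher and 106 lower, 197 by at least log2 1, with no overlap in 270 of them and in 21.5% of all genes. It was 704 without high-cholesterol replicate 1, 59 without replicate 2, 29 without replicate 3, 90 without control replicate 2 and 86 without control replicate 3, so it rested on replicates 2 and 3. In a fit of these 6 libraries alone limma called 0, with 0.114 as the lowest adjusted p among the genes named (1363 genes had an unadjusted p under 0.05 in the fit of all libraries). With FPKM as deposited 1111 were called, 78 higher and 1033 lower. The median of all genes was then log2 −0.47, so directions here are relative to that median. Ovary and germline genes stood at a mean log2 level of 4.22 in high-cholesterol replicate 3 and 1.96 in replicate 2, the libraries in which the lipid genes were highest, against 0.543 in replicate 1.

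Posterior Ctr1B rose from 37.8 ± 9 to 1829 ± 661 (log2 5.51, SE 0.436, adjusted p = 8.62e-08). Posterior MtnA fell from 3563 ± 1840 to 280 ± 107 (log2 −3.63, adjusted p = 0.00619; 0.0684 without high-cholesterol replicate 3). Poxm (log2 2.18) overlaps Ctr1B and may hold its reads. Npc2e rose from 2549 ± 771 to 8199 ± 1370 (log2 1.72, adjusted p = 0.01; 0.112 without high-cholesterol replicate 3 and 0.056 on FPKM as deposited). It was 1 of 14 sterol genes to rise, against 2 rises and 1 fall adjusted over the list alone (fry adjusted p = 0.366). Npc1b (950 ± 535 against 314 ± 20.4) was not called (log2 1.37, adjusted p = 0.189), nor was Npc2b (−0.57, 0.239). Without high-cholesterol replicate 1 both were (1.98, 0.00883, and −0.85, 0.00977). AttC fell from 5.87 ± 2.16 to 0.308 ± 0.256 (log2 −2.37, adjusted p = 0.000172), the only call among 18 antimicrobial genes over all genes tested. The list moved down (1 rise and 2 falls adjusted over the list alone; fry adjusted p = 0.028; adjusted p = 0.0996 with an estimated correlation). The other large rises were in Amyrel (3.63), the EGFR antagonist kek1 (2.81), CG10621 (2.63) and CG42329 (2.48). Falls were in CG6337 (−4.55), CG16712 (−4.07), CG31091 (−3.75) and CR44404, listed at 0 in all 3 libraries. All of these but CG16712 and CG31091 lost their call without high-cholesterol replicate 3 (0.113 for Amyrel).

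The posterior count was 73 genes, 46 higher and 27 lower, 62 by at least log2 1, with no overlap in 71 of them and in 13.7% of all genes. It was 249 without high-cholesterol replicate 1, 16 without replicate 2, 15 without replicate 3, 210 without control replicate 1, 13 without control replicate 2, and 21 without control replicate 3. A fit of the 6 libraries alone called 4. The deposited scale gave 62, 31 higher and 31 lower, with the median at log2 −0.20. No Notch gene passed (nct log2 0.23, adjusted p = 0.744; Psn 0.26, 0.845; fng −0.24, 0.852; fry adjusted p = 0.882). No enteroendocrine gene passed either (sc −0.55, 0.38; NPF −0.91, 0.647; CCHa1 −0.53, 0.679; fry adjusted p = 0.837), nor did a stem cell gene (mira 0.91, 0.644; Dl −0.29, 0.89; Sox21a −0.41, 0.915; fry adjusted p = 0.965). Limma gave 827 genes an unadjusted p under 0.05. Of the digestive lipases CG31091 was the only call, against 4 falls adjusted over the list alone (fry adjusted p = 0.14; CG6271 log2 −1.98, adjusted p = 0.185, or 0.0219 with a pseudocount of 5).

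**Figure D3:**
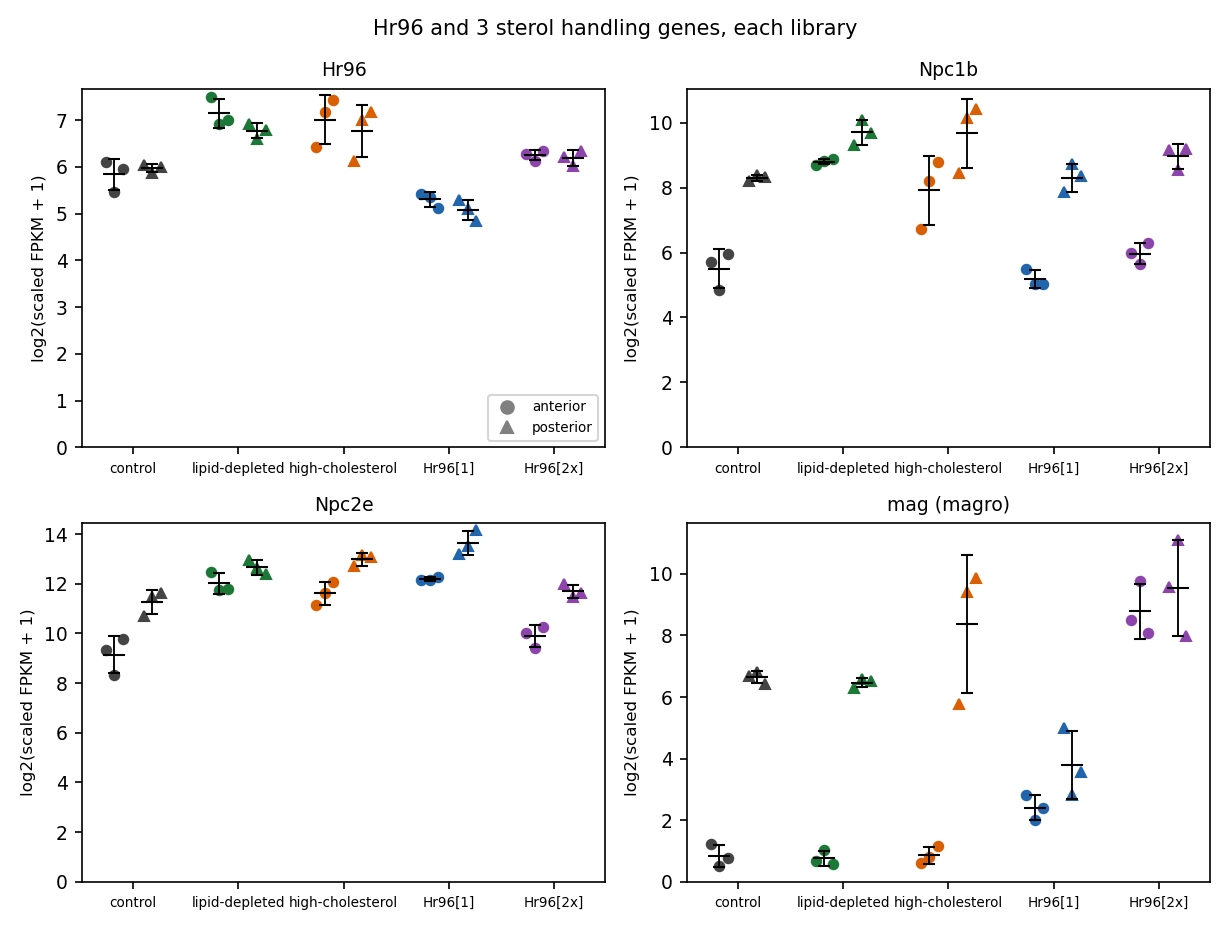
Levels of Hr96, Npc1b, Npc2e and mag in each library, as log2(scaled FPKM + 1), by condition and region; points are libraries and black dashes with bars are mean ± SD of 3. Anterior Npc2e is 4251 ± 1290 scaled FPKM on the lipid-depleted diet and 616 ± 283 in control, and anterior mag is 502 ± 326 in Hr96[2x] and 0.826 ± 0.475 in control.

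Hr96[1] was compared with wild type on the control diet to show what depends on the receptor gene. Wild type was y[1]w[1], so strain background and the allele enter together. Anterior epsilonTry fell from 6026 ± 1680 to 1.77 ± 0.794 (log2 −11.09, SE 0.617, adjusted p = 6.36e-12). The α-glucosidase gene tobi (FBgn0261575, 3R, 25344761 to 25346921) rose from 0.713 ± 0.145 to 360 ± 103 (log2 7.68, adjusted p = 2.26e-11). CG34212 (log2 9.26), CG1678 (9.03), CG45080 (7.80) and CG18404 (7.03) rose, and CG11893 (−8.13), CG43348 (−6.79), CG7900 (−6.00) and CG4302 (−5.80) fell. The short RNAs mir-4940 (105 bases, log2 7.84) and snoRNA:Me18S-A425 (84 bases, −7.75) are uncertain.

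Among sterol genes in anterior Hr96[1], Npc2e rose from 616 ± 283 to 4662 ± 268 (log2 3.04, adjusted p = 1.11e-06) and Npc2f from 51.3 ± 45.5 to 341 ± 29.6 (3.17, 0.00115). LpR1 rose by log2 1.38 (adjusted p = 0.0455; 0.172 without Hr96[1] replicate 2 and 0.116 on FPKM as deposited), while LpR2 fell (−1.54, 0.000257). In all 5 of 14 rose and 1 fell, against 5 and 2 adjusted over the list alone. The list moved up (fry adjusted p = 0.0244; adjusted p = 0.834 with an estimated correlation; 0.284 on FPKM as deposited). Oxidative phosphorylation genes rose, 43 of 62, or 51 adjusted over the list alone (fry adjusted p = 0.0207; adjusted p = 0.834 with an estimated correlation; 0.284 on FPKM as deposited). Among them were CG7712 (50.1 ± 6.65 to 117 ± 20.2, log2 1.20), Pdsw (1.18) and CG34172 (0.659 ± 0.696 to 7.30 ± 5.36). Visceral muscle markers stood at a mean log2 level of 5.41, 5.01 and 5 in the same Hr96[1] libraries, above the controls (4.28, 4.57 and 4.39; fry adjusted p = 0.148). Cytosolic ribosomal protein genes rose, 48 of 81, or 68 adjusted over the list alone (fry adjusted p = 0.0303; adjusted p = 0.834 with an estimated correlation; 0.284 on FPKM as deposited). The largest rises were in RpL24-like (1.21), RpL23A (1.17) and RpS21 (1.15). Of these RpL23A, RpS21, CG34172 and Pdsw lost their call on FPKM as deposited (0.0602, 0.0888, 0.0559 and 0.055), and RpL23A (0.0742) and RpS21 (0.0576) without Hr96[1] replicate 3.

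Some Notch pathway genes fell in anterior Hr96[1]. The ligase gene mib1 (FBgn0263601, 3L, 16006552 to 16011812) fell from 18.7 ± 1.97 to 8.42 ± 0.624 (log2 −1.06, adjusted p = 8.74e-06), pen-2 by −0.78 (adjusted p = 0.0051) and nct by −0.54 (adjusted p = 0.00976; 0.0662 without control replicate 1). These 3 of 15 were also the count adjusted over the list alone (fry adjusted p = 0.148, down, median log2 −0.18 and mean 0.00). The peptide gene Tk rose from 39.4 ± 15.7 to 113 ± 28.8 (log2 1.53, adjusted p = 0.00113) and 7B2 by 0.70 (adjusted p = 0.049; 0.266 on FPKM as deposited and 0.197 without control replicate 3). These were 2 of 13 enteroendocrine genes, 1 adjusted over the list alone (fry adjusted p = 0.432; CCHa1 0.70, 0.103, or 0.0392 without control replicate 1). The progenitor gene esg was called (log2 0.82, adjusted p = 0.0406) with overlapping groups, and the call was lost on FPKM as deposited (0.275) and without Hr96[1] replicate 2 (0.216). No stem cell gene passed adjusted over the list alone (0 of 10; fry adjusted p = 0.698, up, median log2 −0.06), and mira (1.16, 0.104) and the Notch target E(spl)mbeta-HLH (0.93, 0.155) were not called. Without Hr96[1] replicate 1 both were called higher (log2 1.70, 0.0186, and 1.58, 0.00994). Of 12 lipases CG6277 rose (log2 3.44, adjusted p = 0.00621), also 1 adjusted over the list alone (fry adjusted p = 0.48). CG17191 (1.56, 0.058; 0.01 with a pseudocount of 0.1) and CG31089 (−1.16, 0.126; 0.0421 on FPKM as deposited) did not pass. Tubule genes stood high in Hr96[1] replicate 1, with a mean log2 level of 5.63 against 1.44 and 1.39 in replicates 2 and 3, as did ovary genes (4.64 against 0.155 and 0.348). The tubule list was not called (fry adjusted p = 0.182).

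The anterior Hr96[1] count was 1993 genes, 990 higher and 1003 lower, 764 by at least log2 1, with no overlap in 1876 of them and in 40.7% of all genes. It was 1201 without Hr96[1] replicate 2, 1119 without replicate 3 and 1230 in a fit of these 6 libraries alone. With FPKM as deposited 1786 were called, 314 higher and 1472 lower, with the median of all genes at log2 −0.28.

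Posterior mag fell in Hr96[1] from 99.3 ± 12.9 to 15.9 ± 13.1 (log2 −2.85, SE 0.77, adjusted p = 0.0161; 0.0772 without Hr96[1] replicate 2). The call was lost too without replicate 3 or control replicate 2. Digestive lipases fell as a list, 5 of 12, against 1 rise and 5 falls adjusted over the list alone (fry adjusted p = 0.0132; adjusted p = 0.701 with an estimated correlation). Among them were CG31091, from 27.8 ± 15.3 to 0.106 ± 0.117 (log2 −4.55, adjusted p = 2.07e-06), CG6271 (−2.95, 0.00301), CG31089 (−2.60, 0.00241) and CG8093 (−2.27, 0.00067). Npc2e rose (log2 2.36, adjusted p = 4.44e-05), LpR2 (−1.86, 4.07e-05) and Npc2d (−4.12, 0.00448) fell. The sterol list as a whole went both ways, 4 up and 5 down, also 4 and 5 adjusted over the list alone (fry adjusted p = 0.219). The hormone gene Burs (FBgn0038901, 3R, 21769518 to 21770279), listed at 0 in all 3 control libraries, stood at 216 ± 85.2 in Hr96[1] (adjusted p = 5.95e-18). The antimicrobial genes Drs (log2 4.82), Drsl2 (4.72) and Def (3.97; adjusted p = 0.0323, or 0.097 without Hr96[1] replicate 1) rose. So did CG11892 (4.62, 0.0213; 0.0953 without replicate 1) and CG15155 (4.31, 0.0136; 0.0644 without control replicate 1). CG32379, listed at 0 in all 3 Hr96[1] libraries, fell from 66.7 ± 17.8. Also, CG9463 (−6.30), CG11893 (−5.73), CG4302 (−5.61), CG43348 (−5.11) and CG42825 (−5.08) fell.

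In the Notch list of posterior Hr96[1], pen-2 fell from 29.4 ± 2.39 to 14.8 ± 2.86 (log2 −0.96, adjusted p = 0.00145). Smaller falls were in mib1, by −0.47 (adjusted p = 0.0279; 0.193 on FPKM as deposited and 0.107 without control replicate 1) and nct by −0.48 (adjusted p = 0.0305; 0.128 on FPKM as deposited and 0.21 without Hr96[1] replicate 3). The list had 1 rise and 3 falls adjusted over the list alone (fry adjusted p = 0.558, down, though the median was log2 0.11 and the mean 0.03). Tk rose (log2 1.32, adjusted p = 0.00613), 1 of 13 enteroendocrine genes, 1 adjusted over the list alone (fry adjusted p = 0.808, up, with the median at log2 −0.05 and the mean at 0.10). Without control replicate 1, 7B2 was called higher (log2 0.88, 0.0354) and sc lower (−0.83, 0.022). No stem cell gene passed (esg 0.44, 0.346; mira 0.63, 0.459; E(spl)malpha-BFM 0.60, 0.493; fry adjusted p = 0.558). Oxidative phosphorylation genes had 14 rises of 62, 24 adjusted over the list alone (fry adjusted p = 0.0994). Visceral muscle markers stood at 5.85 to 5.92 there, against 4.83 to 5.08 in control (fry adjusted p = 0.0994). The count was 1077 genes, 419 higher and 658 lower, 511 by at least log2 1, with no overlap in 1049 of them and in 30.3% of all genes. It was 634 without Hr96[1] replicate 3 and 331 in a fit of these 6 libraries alone. Tubule genes stood at a mean log2 level of 5.65 in Hr96[1] replicate 1 against 3.43 and 3.60 in replicates 2 and 3, and at 1.48 to 2.52 in control.

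Hr96[2x] was compared with wild type on the control diet in the same way. Anterior mag rose from 0.826 ± 0.475 to 502 ± 326 (log2 7.95, SE 0.77, adjusted p = 1.29e-07). Rises of similar size were in CG1678 (10.31), CG34212 (10.22), CG45080 (7.59, adjusted p = 0.017; 0.0661 without Hr96[2x] replicate 2), tobi (7.36) and the uncertain mir-4940 (7.75). The cytochrome P450 gene Cyp4p2 (FBgn0033395, 2R, 9237512 to 9239831) fell from 129 ± 17.3 to 0.0676 ± 0.0321 (log2 −6.92, SE 0.137, adjusted p = 4.82e-21). It fell with Cyp6a23 (−5.59), the maltase gene Mal-A4 (−5.32), the drug transporter gene Mdr50 (−5.17), Jon74E (−4.79) and CG31219 (−4.33). Of the 14 sterol genes LpR1 (2.21, 0.00299) and mag rose and LpR2 fell (−1.34, 0.00112), the same 2 and 1 adjusted over the list alone (fry adjusted p = 0.229). Of 12 lipases 1 rose and CG31089 fell (−1.91, 0.0168; 0.104 without Hr96[2x] replicate 3), 1 and 1 adjusted over the list alone (fry adjusted p = 0.201). CG6295 was not called (1.63, 0.0977; 0.0373 with a pseudocount of 5).

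**Figure D4:**
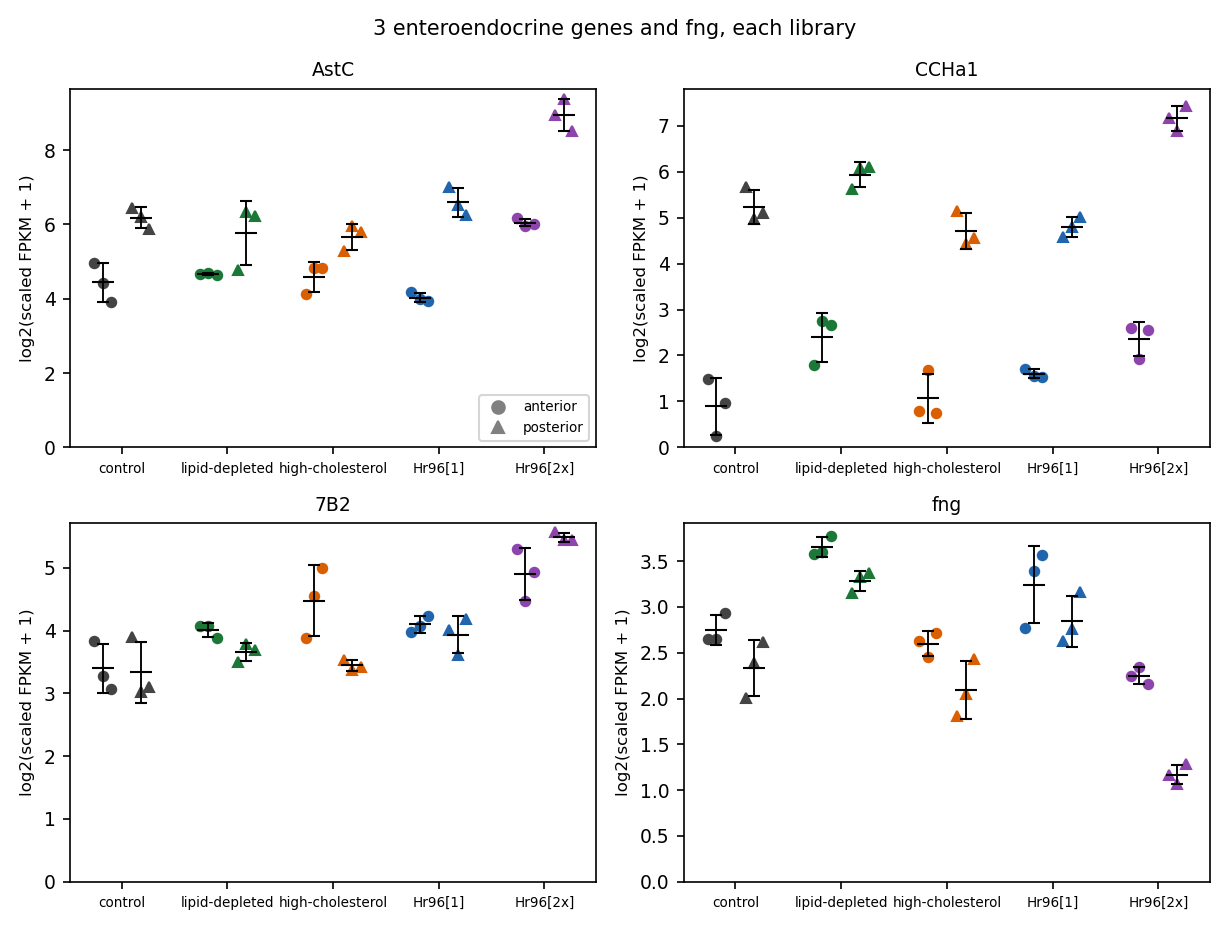
Levels of AstC, CCHa1, 7B2 and fng in each library, as log2(scaled FPKM + 1), by condition and region; points are libraries and black dashes with bars are mean ± SD of 3. Posterior AstC is 506 ± 147 scaled FPKM in Hr96[2x] against 72.1 ± 14 in control, and posterior fng is 8.77 ± 0.751 on the lipid-depleted diet and 1.25 ± 0.167 in Hr96[2x].

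Enteroendocrine genes rose in both regions of Hr96[2x]. In the anterior midgut 5 of 13 rose, 9 adjusted over the list alone (fry adjusted p = 0.00166; adjusted p = 0.795 with an estimated correlation; 0.0579 on FPKM as deposited). CG13565 rose from 79.5 ± 17.7 to 309 ± 54.8 (log2 1.95, adjusted p = 0.0109). AstC (FBgn0032336, 2L, 11076165 to 11081399; 1.61, 0.00141), 7B2 (9.80 ± 3.09 to 29.6 ± 8.68, 0.000233) and the prohormone convertase gene amon (1.40, 0.00167) rose as well. Posterior guts had 9 of 13 rising, 11 adjusted over the list alone (fry adjusted p = 7.16e-06; adjusted p = 0.0634 with an estimated correlation). AstC rose from 72.1 ± 14 to 506 ± 147 (log2 2.77, SE 0.329, adjusted p = 3.19e-06) and 7B2 from 9.51 ± 3.81 to 43.7 ± 2.45 (2.15, 3.19e-06). CCHa1 rose from 37.7 ± 10.4 to 144 ± 27.3 (1.93, 0.000163), the secretory granule gene IA-2 from 9.92 ± 5.61 to 45.2 ± 12.2 (0.0059) and CCHa2 by log2 3.37 (0.00507). The rise did not differ between regions by the list test (fry adjusted p = 0.875). A higher level in bulk RNA does not separate more cells from more RNA per cell.

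Several signalling and immune genes were lower in Hr96[2x]. Antimicrobial and PGRP genes fell in the anterior midgut (1 up and 4 down of 18, the same adjusted over the list alone; fry adjusted p = 0.0293; adjusted p = 0.795 with an estimated correlation). AttC was listed at 0 in all 3 libraries, and PGRP-SD (−2.81, 0.00101) and the immune regulator pirk (−2.55, 0.00125) fell. They fell in the posterior midgut as well (1 up and 5 down, 1 and 6 adjusted over the list alone; fry adjusted p = 0.00357; adjusted p = 0.573 with an estimated correlation). AttC was again at 0, and PGRP-SD (−2.48, 0.00413) and PGRP-SC1b (−2.13, 0.0163; 0.111 without Hr96[2x] replicate 2) fell. Fat body markers stood at a mean log2 level of 1.83, 2.65 and 2.15 in the same libraries against 6.32, 2.90 and 3.73 in control (fry adjusted p = 0.182). Of 13 JAK/STAT and EGFR genes 4 fell in the anterior midgut, 4 adjusted over the list alone (fry adjusted p = 0.0293; adjusted p = 0.795 with an estimated correlation). The cytokine genes upd2 (8.34 ± 2.62 to 1.36 ± 0.716, −1.99, adjusted p = 3.24e-05) and upd3 (−1.76, 0.0128; 0.0874 without control replicate 3) were among them. The fall of rho (−1.48, 0.0447) lost its call without any single library but control replicate 2 (0.222 without control replicate 3). Oxidative phosphorylation genes rose there, 30 of 62 and 50 adjusted over the list alone (fry adjusted p = 0.0192; adjusted p = 0.795 with an estimated correlation; 0.602 on FPKM as deposited). Examples were CG7712 (1.62), CG30354 (1.87) and l(1)G0230 (0.96, adjusted p = 0.00411; 0.259 on FPKM as deposited).

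In the Notch list mib1 fell in both regions of Hr96[2x] (anterior 18.7 ± 1.97 to 9.5 ± 1.79, log2 −0.92, adjusted p = 6.26e-05; posterior −0.55, 0.00965, or 0.065 on FPKM as deposited and 0.0804 without Hr96[2x] replicate 2). Posterior fng fell from 4.13 ± 1.06 to 1.25 ± 0.167 (log2 −1.17, SE 0.189, adjusted p = 0.000172) and pen-2 by −0.69 (adjusted p = 0.0193; 0.123 without Hr96[2x] replicate 3). Anterior E(spl)m6-BFM rose (1.95, 0.00332) and pen-2 was not called (−0.53, 0.0534; 0.0026 on FPKM as deposited). The list gave 1 rise and 1 fall of 15 in the anterior midgut, also 1 and 1 adjusted over the list alone (fry adjusted p = 0.394). It gave 1 rise and 3 falls in the posterior one, 2 and 3 adjusted over the list alone (fry adjusted p = 0.361). The enteroblast gene klu fell (anterior −0.80, 0.0221, or 0.0835 without control replicate 2; posterior −0.86, 0.0187, or 0.0828 without control replicate 3), 1 of 10 progenitor genes in each region and 1 adjusted over the list alone. There was no call for Sox21a (−0.56, 0.335), mira (0.74, 0.361 and 1.29, 0.114, the latter 0.0389 with the replicate number as a block) or Dl (posterior 0.67, 0.0943; 0.0296 after quantile normalization). The list test gave 0.869 and 0.688.

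In posterior Hr96[2x] mag read 757, 2207 and 253 against 99.3 ± 12.9 in control (log2 2.91, SE 0.77, adjusted p = 0.0139; 0.114 without Hr96[2x] replicate 2). This was the opposite direction to Hr96[1]. Npc2b rose from 21.8 ± 3.59 to 57.7 ± 1.61 (1.38, 4.19e-05) and LpR2 fell (−1.04, 0.0112). The sterol list had 2 rises and 1 fall, also 2 and 1 adjusted over the list alone (fry adjusted p = 0.716). Among lipases CG31091 (−3.81, 2.58e-05), CG6271 (−3.16, 0.00166) and CG8093 (−2.05, 0.00162) fell. In all 1 was up and 5 down of 12, against 1 and 6 adjusted over the list alone (fry adjusted p = 0.0777). The gene p24-2 (FBgn0053105, 3R, 9691903 to 9692794), listed at 0 in all 3 control libraries, stood at 77.1 ± 8.68 (adjusted p = 4.27e-21). CG14205 (5.32), GstE1 (4.64), Drsl2 (4.57), CG11700 (4.53) and Jon66Ci (4.48) rose. Cyp4p2 fell from 134 ± 25 (log2 −6.96, adjusted p = 4.27e-21), with Mdr50 (−5.69), CG32379 (−5.23), CG42825 (−4.86), Cyp6a23 (−4.86) and the Integrator subunit gene IntS12 (−4.75).

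Hr96[2x] gave 1532 called genes in the anterior midgut, 718 higher and 814 lower, 647 by at least log2 1, with no overlap in 1469 of them and in 36.2% of all genes. This was 1004 without control replicate 3 and 847 in a fit of these 6 libraries alone. With FPKM as deposited 2349 were called, 233 higher and 2116 lower, with the median of all genes at log2 −0.40. The posterior count was 934, 344 higher and 590 lower, 487 by at least log2 1, with no overlap in 911 of them and in 33.7% of all genes. It was 615 without Hr96[2x] replicate 1, and the median of all genes on FPKM as deposited was log2 −0.11.

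Both Hr96 strains moved many of the same genes. Of 878 anterior genes called in both, 853 went the same way. Of these 385 were higher in both, where independent lists would share 85.3, and 468 lower, against 98.0. The correlation of fold changes across genes, which are not independent replicates, was 0.58, against 0.498 in 200 simulations of unchanged groups with these controls. The covariance was 0.396 against 0.0904. Of 400 posterior genes called in both, 383 went the same way (90 higher against 17.3, 293 lower against 46.6). Correlation was 0.433 against 0.501 and covariance 0.228 against 0.0912. The 3 controls cannot be split with 2 on each side, so part of the excess may come from the shared controls. On both diets 65 anterior genes were called, all the same way (45 higher against 3.1, 20 lower against 1.6). Correlation was 0.4 against 0.498 and covariance 0.138 against 0.0904. Of 25 posterior ones 24 went the same way (covariance 0.0827 against 0.0912). Anterior high cholesterol went with Hr96[2x] in 135 of 148 shared calls (covariance 0.162) and Hr96[1] in 119 of 137 (0.136). The lipid-depleted diet did in 55 of 102 and 73 of 118.

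The difference between regions in each response was tested as an interaction. On the lipid-depleted diet 48 genes differed, 12 with a higher and 36 with a lower response in the posterior midgut (7 and 40 of 47 on FPKM as deposited, median log2 −0.01). The first was CG18179 (FBgn0036023, 3L, 9639271 to 9640140), which fell from 273 to 9.30 in the anterior midgut and stood at 2.67 and 9.75 in the posterior one. On high cholesterol 2 genes differed, CG18179 and CG6283. In Hr96[1] 34 differed, 10 higher and 24 lower, and in Hr96[2x] 30, 8 higher and 22 lower (15 and 18 of 33 on FPKM as deposited, median log2 0.30). With the replicate number as a block, which the labels do not call a pairing, the counts were 100 for the lipid-depleted diet (41 of the 48 among them), 3 for high cholesterol (1 of the 2, without CG18179, adjusted p = 0.121), 239 for Hr96[1] (all 34) and 116 for Hr96[2x] (all 30). In Hr96[1] the sterol list moved lower in the posterior than in the anterior midgut (1 fell, 3 adjusted over the list alone; fry adjusted p = 0.0244; adjusted p = 0.129 with an estimated correlation; 0.342 on FPKM as deposited). So did the digestive lipases (1 fell, against 1 rise and 5 falls adjusted over the list alone; fry adjusted p = 0.0315; adjusted p = 0.129 with an estimated correlation). The Notch list did not differ between regions on the lipid-depleted diet (fry adjusted p = 0.677). Counts that moved over 1.5 times without 1 library were, for the lipid-depleted diet, 29, 26, 27 and 31 without posterior lipid-depleted replicates 2 and 3 and control replicates 1 and 2, and 29, 29 and 30 without anterior lipid-depleted replicates 2 and 3 and control replicate 2. For Hr96[1] they were 55 without posterior replicate 1 and 117, 18 and 22 without anterior replicates 1, 2 and 3, and for Hr96[2x] 47 without anterior replicate 3.

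The other lists passed in no comparison. Their lowest fry adjusted p was 0.0814 for enterocyte genes (posterior against anterior), 0.0994 for amylases and maltases, detoxification enzymes, visceral muscle and Malpighian tubule genes (posterior Hr96[1]), and 0.112 for regional transcription factors (posterior against anterior). It was 0.121 for the cell cycle and 0.297 for heat shock proteins (anterior high cholesterol), 0.148 for ecdysone signalling (anterior Hr96[1]), and 0.158 for fat body and 0.383 for ovary and germline genes (posterior Hr96[1]).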

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

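The counts of other splits and the shared-control covariances were planned before their results were seen, and the draws with equal numbers and the tests of replicate 1, of present or absent genes and of tubule tissue were chosen after.

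Responses that differed between regions are given first, as log2 differences of the posterior minus the anterior response, each from the interaction test of limma. On the lipid-depleted diet 48 genes differed, led by CG18179 (6.23, adjusted p = 1.68e-07), wntD (−2.96), CG43208 (−3.29), CG43729 (2.36; adjusted p = 0.073 with a pseudocount of 0.1) and CG10051 (−3.53). On high cholesterol 2 genes differed, CG18179 (3.09) and CG6283 (−7.51), with CG2747 (−2.07, adjusted p = 0.0968), CG17191 (−3.92, 0.222) and CG15865 (1.13, 0.394) next and not called. Without anterior high-cholesterol replicate 1 CG2747 (0.00751) and CG17191 (0.00603) were called. Neither call held in a fit of the compared groups alone (0 genes). The count went to 23 without anterior and 14 without posterior high-cholesterol replicate 1. It was 4 without control replicate 1 of either region and 1 without anterior high-cholesterol replicate 3. It was 0 without replicate 2 of any compared group, posterior high-cholesterol replicate 3 or anterior control replicate 3.

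In Hr96[1] 34 genes differed between regions: epsilonTry (9.62), which fell from 6030 to 1.77 in the anterior midgut and was at 4.98 and 1.44 in the posterior one, tobi (−7.00), CG32379 (−5.88), Burs (2.23; adjusted p = 0.444 with a pseudocount of 0.1) and iotaTry (−4.88). The sterol list (fry adjusted p = 0.0244) and digestive lipases (0.0315) differed too, but not with an estimated correlation (0.129 each). CG32379 stood at 0.124 in anterior control, so it had no room to fall there in either strain. In Hr96[2x] 30 genes differed: tobi again (−6.30), which rose from 0.713 to 393 in the anterior midgut and stood at 0.651 and 2.56 in the posterior one, CG4835 (−3.24; adjusted p = 0.48 with a pseudocount of 0.1), CG32379 (−5.12), CG15431 (−3.10) and CG13397 (−1.83).

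Splits of the same 6 libraries number 10, the real one included, too few for a share under 0.05. The real split gave 1222 genes for the regions (highest other 1), 264 and 319 for the lipid-depleted diet in the anterior and posterior midgut (3 and 0), 293 and 73 for high cholesterol (39 and 135), 1993 and 1077 for Hr96[1] (5 and 1) and 1532 and 934 for Hr96[2x] (1 and 15). The real split gave the most genes in all of these but posterior high cholesterol, where 2 of 10 splits, again counting the real one, gave as many or more. The other one exchanged replicate 1 of control and of high cholesterol. For the differences between regions 100 splits were used, the real one included. Counting the real one, as many genes came from 5 for the lipid-depleted diet (highest other 747) and 9 for high cholesterol (802). It was 17 for Hr96[1] (2953) and 11 for Hr96[2x] (1352). Every other draw that reached the real count exchanges unequal numbers of condition libraries in the regions, which turns the response common to both into a difference, a structure of the samples, so these shares decide nothing about chance. Draws with equal numbers in both regions gave at most 0, 1, 4 and 3 genes in the same order, but their mixed groups hold the response as spread, which lowers calls, so whether chance can be excluded stays open. Draws ignored replicate numbers, which the labels do not call a pairing.

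The libraries of replicate 1 on high cholesterol changed less than replicates 2 and 3. Over genes called without replicate 1, its change relative to theirs was 0.115 in the anterior and −0.0524 in the posterior midgut, while the other 3 conditions ran from 0.609 to 0.811 and from 0.644 to 1.04. Against controls 2 and 3 instead of control 1 it was 0.434 and 0.391, with the others from 0.7 to 0.927 and from 0.668 to 0.97. A feature of all replicate 1 libraries as the whole cause is argued against in the anterior midgut, where the gap to the lowest other condition exceeded the range among the others with either baseline (0.494 over 0.202, and 0.266 over 0.227), by a bound set after a first one had left it open. In the posterior midgut it cannot be told apart, since the gap was 0.696 over 0.394 with control 1 but 0.277 under 0.302 with controls 2 and 3. A control library in its place is argued against by the metal genes, with Ctr1B above or a metallothionein below all 3 control libraries in 12 of 12 comparisons. This test was chosen after a first one, in which a held-out control library gave −0.0369 to 0.319 in the anterior midgut and −0.0331 to 0.443 in the posterior one, against 0.33 to 0.434 and 0.326 to 0.391 for high-cholesterol replicate 1, ranges that overlap in the posterior midgut only. Replicate 1 was the lowest of the 3 high-cholesterol libraries in 8 of 10 metallothionein comparisons (anterior MtnA 92.5 against 442 and 547, MtnC 203 against 3790 and 6630; the exceptions were posterior MtnA, 347 against 338 and 156, and MtnB, 28.3 against 170 and 24.5). Its Ctr1B was lowest too (318 against 537 and 480, and 1070 against 2240 and 2170). A weaker or otherwise different exposure was not tested and stays open.

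Genes called in both Hr96 strains went mostly the same way, although Hr96 itself was called only in posterior Hr96[1] (lower, adjusted p = 0.0893 without replicate 3). The covariance of fold changes, 0.396 in the anterior and 0.228 in the posterior midgut, exceeded the highest of 200 simulations (0.123 and 0.122). Control deviations common to many genes were not tested and stay open. CG31219 alone of the 975 genes (0.103%) was at most 0.1 in all libraries of one background and above 1 in all others. Genes of only 1 region cannot pass, so the share lacking in one background is open. A difference of background between y[1]w[1] and both strains and a shared effect of the altered Hr96 gene are confounded and stay open.

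Renal tubule genes stood high in replicate 1 of Hr96[1] in both regions. The tubule enzyme gene Uro (FBgn0003961, 2L, 7780085 to 7781415) read 160 in anterior replicate 1 against 0 and 0.117 in replicates 2 and 3, and 171 in posterior replicate 1 against 23.2 and 32.7. If tubule tissue came along in the dissection, tubule genes outside that list should follow, and replicate 1 was highest in 8 of 8 comparisons of CapaR, Oatp58Db, Oatp58Dc and NaPi-T (Oatp58Dc 40.7 against 0 and 0.0229 in the anterior and 48.1 against 9.42 and 9.74 in the posterior midgut). In the list anterior Irk1 did not follow (41.6 against 51.1 and 45.5). Carried-along tissue is a candidate source, as a hypothesis. As the cause of the anterior Hr96[1] calls it is argued against, since 88.4% were still called without this library and tubule genes then stood within the controls (1.39 and 1.44 against 1.00 to 2.36). In the posterior midgut 86.6% were still called, but tubule genes stayed above the controls in replicates 2 and 3 (3.43 and 3.60 against 1.48 to 2.52), so the cause cannot be told apart there. A higher tubule gene level in the gut of these flies stays open, as no test was run for it.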

How the results depend on the processing

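Fits of replicates 2 and 3 alone, or averaged, were chosen after the data were seen; the other settings were planned. Of called genes named, 0 changed sign in any setting. Of all calls, FPKM as deposited turned the direction of 52 for Hr96[2x], 5 for Hr96[1] and 4 for high cholesterol in the anterior midgut and 7 between regions, and quantile normalization that of 1 for anterior Hr96[1]. The share that kept its side of the threshold was 303 of 304 tests with failed estimates kept, 300 of 304 with robust moderation, 290 of 303 after quantile normalization, and 276 of 303 on FPKM as deposited (21 lost and 6 gained). It was 290 and 291 of 304 with pseudocounts of 0.1 and 5, 288 of 304 with no filter, 262 of 264 at a mean of 5, and 1687 of 1944 with 1 library left out (237 lost and 20 gained). The largest losses came in fits of the compared groups alone (87 of 304 lost, among them aph-1 on the lipid-depleted diet, 0.0576 and 0.102, and posterior mag in Hr96[1], 0.0565, and Hr96[2x], 0.0785) and with replicates 2 and 3 averaged (106 of 304 lost). Of the counts, robust moderation, a pseudocount of 5, quantile normalization and failed estimates kept moved none by over 1.5 times.

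FPKM as deposited gave 1111 genes for high cholesterol and 2349 for Hr96[2x] in the anterior midgut. It turned the direction of the unfolded protein response list between regions (fry adjusted p = 0.934), as the median of all genes moved by log2 0.35. Of the list tests called by fry, camera with an estimated correlation kept 2, and those lost were not tested for a cause.

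A fit of only the compared groups has fewer samples behind each variance. It called 148 and 185 genes for the lipid-depleted diet in the anterior and posterior midgut, 0 and 4 for high cholesterol, 1230 and 331 for Hr96[1], 847 for Hr96[2x] in the anterior midgut, and 0 and 10 for the region differences of high cholesterol and Hr96[2x]. It raised the region differences of the lipid-depleted diet to 72 (37 of the 48) and of Hr96[1] to 40 (18 of the 34), and gave 1235 between regions (903 of the 1222). Without replicate 1 in any group, 480 genes were called for the lipid-depleted diet in the anterior midgut (191 of them among the 264), 1368 and 1084 for high cholesterol (287 of the 293 and 73 of the 73), and 128, 119, 242 and 80 for the region differences of the lipid-depleted diet, high cholesterol, Hr96[1] and Hr96[2x]. The cause was not tested, though replicates 2 and 3 were closest in 8 of 10 groups, with an SD of 0.155 to 0.657 against 0.426 to 0.674 for pairs with replicate 1. If replicates 2 and 3 were made from the same tissue, that fit would overstate its calls. With both averaged into 1 library, so with fewer samples, 611 genes differed between regions, 53 and 94 were called for the lipid-depleted diet, 0 and 2 for high cholesterol, 681 and 361 for Hr96[1], 584 and 352 for Hr96[2x], and 8, 0, 5 and 6 for the region differences in the same order.

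The pseudocount and the filter, which also set the number of genes tested (15281 with none and 6248 at a mean of 5), changed the region differences. With a pseudocount of 0.1 the count was 29 for the lipid-depleted diet and 16 for Hr96[1]. With no filter it was 0 for high cholesterol, 55 for Hr96[1] and 61 for Hr96[2x], and at a mean of 5 it was 12 for Hr96[1] and 19 for Hr96[2x]; the cause was not tested.

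The labels number replicates 1 to 3 in every group without saying that a number marks a shared source. With the replicate number as a block, 2267 genes differed between regions on the control diet, and the region differences were 100 for the lipid-depleted diet, 239 for Hr96[1] and 116 for Hr96[2x]; no other count moved by over 1.5 times. Deviations of libraries with the same number correlated at 0.31, 0.038 and 0.26 between regions on the control diet. In no comparison of conditions were all 3 above 0.1. Between regions all 3 were above 0.1 on the lipid-depleted diet (0.2 to 0.39), in Hr96[1] (0.3 to 0.52) and in Hr96[2x] (0.2 to 0.27), a hint from the data that both regions of a number came from the same flies.

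With 1 library left out, where a group of 2 remains, counts ran from 864 to 1129 for the regions, 115 (without control replicate 2) to 202 and 146 (without control replicate 1) to 306 for the lipid-depleted diet. They ran from 29 (without replicate 3) to 704 (without replicate 1) and 13 (without control replicate 2) to 249 (without replicate 1) for high cholesterol, from 1119 (without replicate 3) to 2346 and 634 (without replicate 3) to 1301 for Hr96[1], and from 1004 (without control replicate 3) to 1354 and 615 (without replicate 1) to 880 for Hr96[2x], anterior before posterior. For the region differences they ran from 26 (without posterior lipid-depleted replicate 3) to 51, from 0 (without posterior high-cholesterol replicate 3, among others) to 23 (without anterior high-cholesterol replicate 1), from 18 (without anterior Hr96[1] replicate 2) to 117 (without anterior replicate 1), and from 24 to 47 (without anterior Hr96[2x] replicate 3). Genes below a mean of 1 were tested only with no filter, and as absolute depth is unknown, what it hides among them was not measured.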

Other observations

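The test of the metal genes and the genes in the lists of shared and opposite calls were chosen after their values were seen.

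A small set of genes was called the same way in all 4 conditions against control, 14 in the anterior midgut (9 higher and 5 lower) and 6 in the posterior one (2 higher and 4 lower). All 4 comparisons use the same control libraries, and no such count was simulated, so these counts do not show a common response. Among anterior genes the glutathione S-transferase gene GstE3 stood at 266 in control and 1030, 1040, 1250 and 706 on the lipid-depleted diet, on high cholesterol, in Hr96[1] and in Hr96[2x]. In the posterior midgut Pdxk rose in the same order from 84.2 to 187, 258, 267 and 319.

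Of the genes called in both Hr96 strains, 25 in the anterior and 17 in the posterior midgut went in opposite directions. Anterior epsilonTry was at 6030 in control, 1.77 in Hr96[1] and 35000 in Hr96[2x]. Posterior mag was at 99.3, 15.9 and 1070 and anterior CG4563 at 20.7, 176 and 4.86.

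High cholesterol raised Ctr1B and lowered MtnA in both regions, a pair that the metal-responsive factor MTF-1 drives in opposite directions with metal supply. The lipid-depleted diet did the same in part (Ctr1B log2 1.74, adjusted p = 0.0268, and 3.57; posterior MtnA −3.34, adjusted p = 0.0026, and MtnC −3.94, adjusted p = 0.013). A lower supply of copper or zinc in the altered food is a candidate explanation, and it predicts that the other metallothionein genes fall on high cholesterol too. All 8 tests of MtnB, MtnC, MtnD and MtnE in both regions had negative log2 changes. Mean FPKM was lower in 7, all but anterior MtnC (log2 −0.15). Only 1 passed when adjusted over these genes alone (anterior MtnD, adjusted p = 0.0281). On the lipid-depleted diet 4 of 8 did (anterior MtnC 0.035 and MtnD 0.0292; posterior MtnC 0.00104 and MtnE 0.0435). On high cholesterol MtnC was below all controls in replicate 1 only. Anterior replicates 2 and 3, with more Ctr1B, exceeded them (3790 and 6630 against up to 3440), against the prediction. Ctr1B was called higher in posterior Hr96[2x] (log2 1.38, adjusted p = 0.0421), but not without replicate 1 (0.352), so this has no weight here. Anterior MtnA rose in Hr96[1] (1660 to 7640, adjusted p = 0.0153) and MtnB fell in Hr96[2x] (173 to 22.1, 0.0443). The hypothesis stays open. The metal content of the diets is not given in the sources used here.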
